A study of Mus musculus with 6 samples.

How the data were processed

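RNA of pancreatic islets from male mice aged about 20 weeks was sequenced in 6 libraries, 3 labelled control (Pdgfra fl/fl without Pdx1-Cre) and 3 labelled KO (Pdgfra fl/fl with Pdx1-Cre). Libraries were made with an mRNA kit, per the labels' protocols. The labels give the cell type as beta cell and the tissue as islet and name no sorting step. The titles number the mice within each group and do not state that each library is a separate animal, so p-values measure the spread between these libraries. No control with Cre and unfloxed Pdgfra is among the samples, so an effect of Cre cannot be separated from that of Pdgfra deletion. The column names of all 3 KO libraries, and of 0 controls, end in a suffix that the labels do not explain.

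The authors deposited a table of raw read counts per gene for the 6 libraries. Per the submitters' processing notes, STAR 2.7.9 and featureCounts 2.0.0 were used with the builds GRCm38.p6 and mm10. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so counts of overlapping, antisense and near-identical genes are uncertain. The table holds 55401 gene identifiers, of which 55141 were given a symbol from a gene name table and 54349 matched it with their version. Gene types came from GENCODE vM21. A symbol shared by several identifiers was given to the protein-coding one with the most counts, and 107 identifiers kept their own. Identifiers without a symbol held at most 0.00998% of a library's counts.

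Library totals ran from 15026094 to 25299689 counts. Shares of counts were compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1, and had 95% Wilson intervals. Levels are CPM scaled by TMM factors. Libraries were checked for duplicates by a chi-square test of their counts, and the closest pair had a chi-square of 16.0 per degree of freedom. The genes Xist, Kdm5d, Eif2s3y, Uty and Ddx3y were read in each library as a check of sex, and Xist had at most 1 count.

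The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with TMM normalization and genotype as the only term. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. P-values were adjusted by Benjamini-Hochberg over all 14212 genes, with a threshold of 0.05, and all tests were two-sided. The common biological coefficient of variation was 0.140. Fold changes carry a standard error, and those of Pdgfra, Ins1, Ins2 and Gcg a 95% interval. A gene with 0 counts in a group was compared with a floor of 3 counts over the group.

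There were 20 pathway lists and 15 cell type lists. Lists with at least 5 tested genes were tested with camera on the edgeR fit (limma 3.58.1, preset correlation 0.01) and adjusted within the pathway or cell type lists. They were repeated with an estimated correlation and with fry. Of the 694 genes in the lists, 5 were not found by name. The adipocyte list had 1 tested gene, and it and the sex list were not tested. The named genes were Pdgfra, Pdgfrb, Ins1, Ins2, Pdx1, Mafa, Gcg, Sst, Bax, Bcl2, Ezh2 and Mki67, and up to 12 genes in each direction with the largest change among those past the threshold with mean log2 CPM of at least 1 and no overlap of the groups, filled up to 6 by the smallest p. To these came up to 4 members with the smallest p of each called list, of both apoptosis lists, and of the beta-cell identity, unfolded protein response, PDGF, proliferation and prolactin lists. Some genes that this rule takes are not reported here. Genes without a given name were counted but not described, and Lmo1 was named after its values were seen, since it passed the threshold below the minimum level. Lists, named genes, tests and most alternatives were fixed before the data were examined.

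The alternatives were RLE normalization, no filter on low counts, the replicate number as a block, each library left out in turn, an acinar score as a covariate, acinar genes removed, DESeq2 1.42.0, limma-voom and limma-voom with sample quality weights. The log2 CPM of a ribosomal RNA locus as a covariate and KO 1 alone against the controls were added after seeing the data. The test script was checked on counts simulated for this comparison, with 194 changed genes among 13990 tested. At a log2 fold change of 1 it recovered 62.2% of them and at 2 it recovered 94.8%, and 8.43% of its calls were false. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.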

Results

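RNA was sequenced from pancreatic islets of male C57BL/6 mice aged about 20 weeks. All animals carried 2 floxed copies of Pdgfra, the gene of the platelet-derived growth factor receptor alpha. The 3 control libraries came from mice without Cre, and the 3 libraries labelled KO from mice with Cre under the promoter of Pdx1, a transcription factor of the pancreatic lineage. The comparison asks how islet transcripts differ when Pdgfra is deleted in that lineage, with beta-cell death named in the title of the series. The control libraries held 15026094, 16261331 and 25299689 counts, and the libraries labelled KO held 24316901, 18247741 and 25039394. After a filter on low counts, 14212 genes were tested.

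Pdgfra transcripts were not measurably lower in the libraries labelled KO. Pdgfra (ENSMUSG00000029231.15, chromosome 5, 75152292 to 75198215, GRCm38) had 42, 88 and 116 counts in controls 1, 2 and 3 and 93, 25 and 125 counts in KO 1, 2 and 3. Its level was 4.11 ± 0.91 CPM (counts scaled to library size) in controls and 3.35 ± 1.63 in KO (SD, n = 3 each, exact two-sided permutation p = 0.6, the smallest possible being 0.1). The log2 fold change was -0.26 (SE 0.34, 95% interval -1.03 to 0.50, edgeR adjusted p = 0.869). It rested on KO 2, since without that library the value was 0.04. The table sums reads over all exons of a gene, so transcripts that lack only the deleted exons still count, and Pdgfra therefore gave no check of the genotype labels. Pdgfrb, the related receptor, stood at 13.5 ± 2.1 CPM in controls and 10.9 ± 4.8 in KO (SD, n = 3 each, edgeR adjusted p = 0.830).

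**Figure D1:**
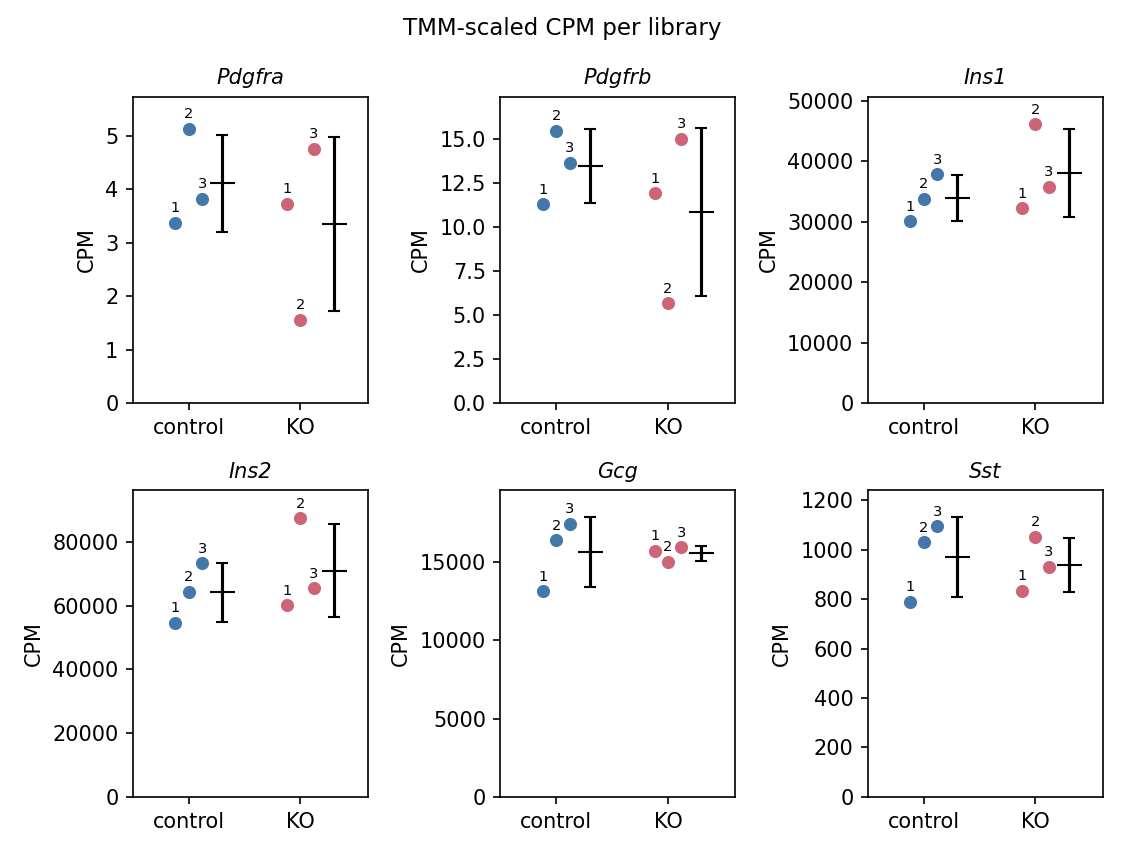
TMM-scaled CPM of Pdgfra, Pdgfrb and the islet hormone genes Ins1, Ins2, Gcg and Sst in each library, with the replicate number beside each point and the group mean and SD as a bar. The 2 groups overlap for all 6 genes, and KO 2 has the lowest Pdgfra and Pdgfrb.

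In the libraries labelled KO, 10 of the 14212 genes differed from controls at an adjusted p under 0.05 (edgeR quasi-likelihood test), of which 1 rose and 9 fell. The gene that rose was Foxi3, a forkhead transcription factor, with 0 counts in every control. Those that fell included Atf5, a stress-response transcription factor, Aars, the cytosolic alanyl-tRNA synthetase, and Aldh1l2, a mitochondrial enzyme of folate metabolism. Aldh1a3, a retinaldehyde dehydrogenase known as a marker of beta cells that lose their identity, also fell. Genes of insulin and of apoptosis did not pass the test.

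Foxi3 (ENSMUSG00000055874.6, chromosome 6, 70956531 to 70961066) had 155, 106 and 170 counts in KO 1, 2 and 3, or 6.43 ± 0.20 CPM (SD, n = 3). Against a floor of 3 counts over the control group it was at least 129-fold higher (edgeR adjusted p = 9.07e-04). Atf5 (chromosome 7, 44812256 to 44816658) fell from 148 ± 9.7 to 45.8 ± 6.9 CPM, a log2 fold change of -1.70 (SE 0.13, adjusted p = 0.00129, lower in 3 of 3 KO libraries than in any control). Kcnf1, a modulatory potassium channel subunit (chromosome 12, 17172100 to 17176888), fell by 2.19 on the log2 scale (SE 0.22, adjusted p = 0.0122). Aldh1a3 (chromosome 7, 66390890 to 66427517) fell from 4.85 ± 1.3 to 1.29 ± 0.24 CPM (log2 fold change -1.93, SE 0.25, adjusted p = 0.0441). Aldh1l2 (chromosome 10, 83487450 to 83534140) fell from 70.1 ± 20 to 27.5 ± 2.1 CPM (log2 fold change -1.34, SE 0.18, adjusted p = 0.0444). Chd5, a chromatin remodeller (chromosome 4, 152338651 to 152390194), fell by 1.16 on the log2 scale (SE 0.16, adjusted p = 0.0451), and Aars (chromosome 8, 111033144 to 111057664) fell by 0.80 (SE 0.10, adjusted p = 0.0273). The other 3 were Lmo1, below the abundance set for named genes at 2.17 ± 0.46 and 0.398 ± 0.037 CPM, and 2 genes without a given name. Of these 2, 1 lay in the zinc finger cluster on chromosome 2 that is described further below. The other, on chromosome 17 (39848103 to 39848827), matched no gene type, so what its reads stand for is uncertain.

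**Figure D2:**
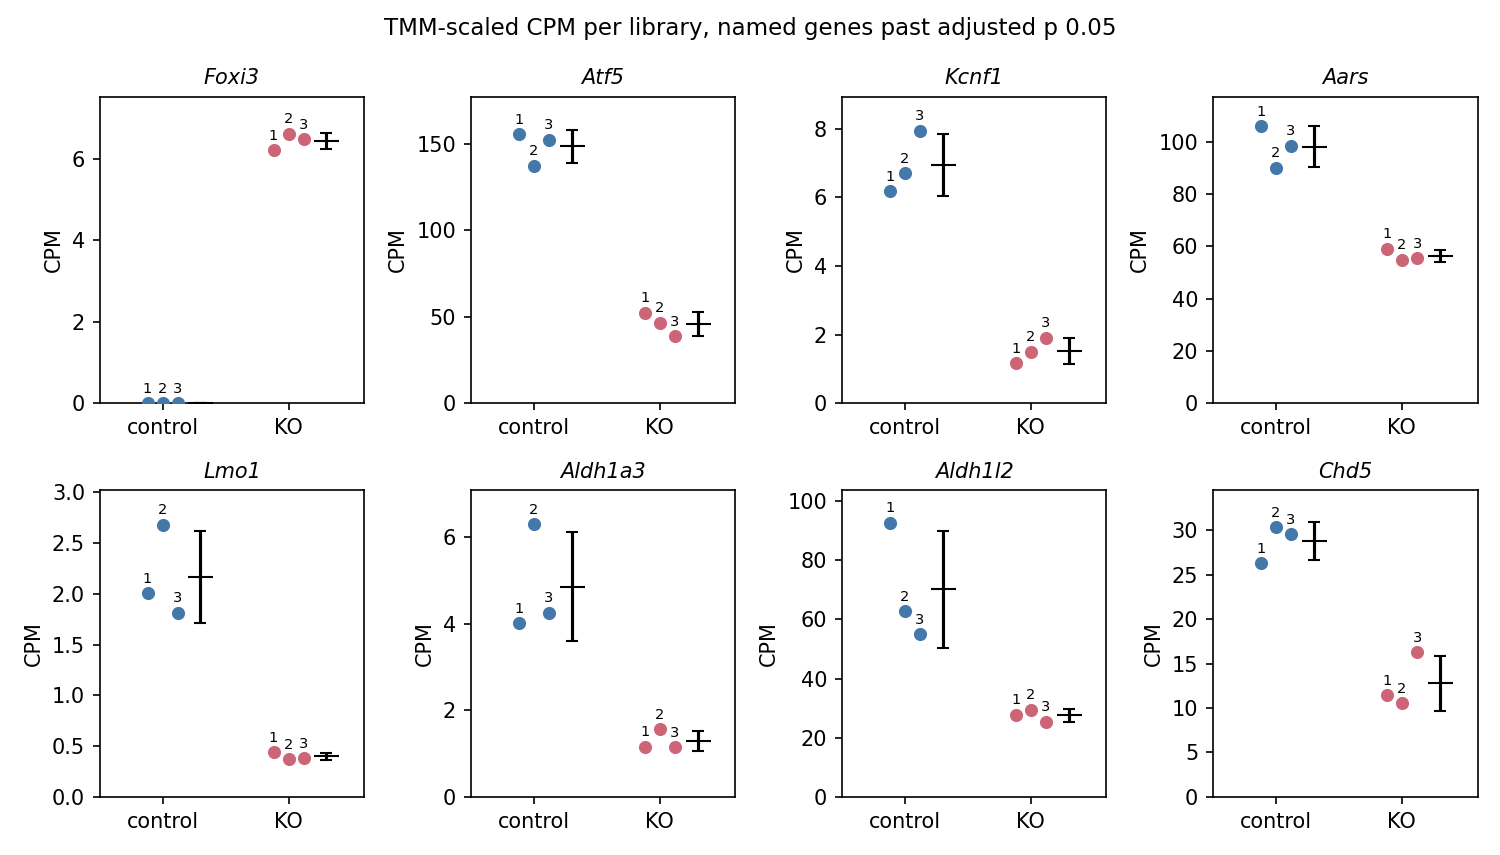
TMM-scaled CPM in each library for the 8 genes with a given name that passed an adjusted p of 0.05, with the replicate number beside each point and the group mean and SD as a bar. The KO points lie on 1 side of the control points in each panel, and Foxi3 is at 0 in all 3 controls.

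Among genes higher in the libraries labelled KO that missed the threshold, with a mean log2 CPM of at least 1 and no overlap of the groups, those with the smallest p were Carmil3, Gadd45b, Six4, Zfp568 and Bub3, with log2 fold changes of 0.62, 1.15, 0.85, 0.79 and 0.59 and edgeR adjusted p from 0.0845 to 0.102. At an unadjusted p under 0.05 there were 1048 genes, 687 higher and 361 lower. The groups did not overlap in 1973 genes (13.9%), where chance gives 10%. The 10 calls fell to between 2 and 6 when 1 library was left out. With log2 CPM of a ribosomal RNA locus as a covariate no gene passed, while the log2 fold changes of Atf5, Kcnf1, Aldh1l2 and Chd5 were -1.49 (SE 0.20), -2.59 (SE 0.38), -1.49 (SE 0.30) and -1.36 (SE 0.28). Their standard errors in the main test were smaller, at 0.13, 0.22, 0.18 and 0.16. Foxi3 had an edgeR adjusted p of 0.0514 with this covariate.

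The islet hormone genes were at similar levels in both groups. Ins1 had a log2 fold change of 0.17 (SE 0.34, edgeR adjusted p = 0.924), Ins2 of 0.15 (SE 0.40, adjusted p = 0.946), Gcg of -0.01 (SE 0.27, adjusted p = 0.994) and Sst of -0.05 (SE 0.17, adjusted p = 0.956). The transcription factors Pdx1 and Mafa had values of -0.04 (SE 0.10, adjusted p = 0.940) and -0.15 (SE 0.11, adjusted p = 0.777). As a list, the 30 tested genes of beta-cell identity were higher in KO (camera adjusted p = 0.0018, adjusted p = 0.645 with an estimated correlation), 25 of them with positive values, but none passed over all genes or adjusted over the list alone. Slc2a2, the main glucose transporter of mouse beta cells, had a value of 0.36 (adjusted p = 0.637), Rfx6 0.22 and Sytl4 0.24. The list was lowest in control 1 (mean deviation -0.21), which had the highest acinar share of counts, 46.0%, and the lowest share of Ins1 and Ins2, 7.04%. The call ended without control 1 (adjusted p = 0.184) or without KO 2 (adjusted p = 0.0684).

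Neither apoptosis list was called. Of the 34 tested pro-apoptotic genes, 16 had positive and 18 negative values (camera adjusted p = 0.569), and 0 passed over all genes or adjusted over the list alone. The 4 with the smallest p were lower in KO, namely Tnfrsf1a (log2 fold change -0.27, adjusted p = 0.633), Bak1 (-0.34, adjusted p = 0.674), Cycs (-0.25) and Fadd (-0.27). Bax had a value of -0.03 (SE 0.12, adjusted p = 0.954). Of the 19 anti-apoptotic genes, 8 had positive and 11 negative values (camera adjusted p = 0.879). Among them were Cflar at 0.26 (edgeR adjusted p = 0.656), Pim3 at 0.43 (adjusted p = 0.671), Birc6 at 0.26 and Akt1 at -0.20. Pim3 passed over all genes with the acinar covariate (0.56, SE 0.08, edgeR adjusted p = 0.0293) but not with DESeq2. Bcl2 had a value of -0.32 (SE 0.22, adjusted p = 0.777).

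As a list, genes of the unfolded protein response were lower in the libraries labelled KO. Of 35 tested, 27 had negative values (camera adjusted p = 8.19e-05, adjusted p = 0.613 with an estimated correlation), none passed over all genes, and 4 fell when adjusted over the list alone. These were Trib3, a pseudokinase induced by stress (log2 fold change -1.51, SE 0.24), Chac1, a glutathione-degrading enzyme (-1.51, SE 0.25), Ddit3, which encodes the transcription factor CHOP (-0.77, SE 0.16), and Atf4, the transcription factor that acts on the other 3 (-0.46, SE 0.11). Over all genes Trib3 and Chac1 passed with DESeq2 and with the acinar covariate, Atf4 with DESeq2 only and Ddit3 with neither. No gene passed with the ribosomal RNA covariate. Of the 8 members with positive values, 1 had an unadjusted p under 0.05, Eif2ak3 (0.66, SE 0.20, edgeR adjusted p = 0.537). The 21 members that are chaperones or folding factors of the endoplasmic reticulum had a median of -0.08, with 15 negative. The mean deviation of the list was highest in control 1 (0.27) and lowest in KO 3 (-0.21), as was that of the acinar list (0.83 and -0.72). The call held without each library in turn, though at an adjusted p of 0.0419 without control 1, and with the ribosomal RNA covariate.

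Genes of proliferation were lower too, with 21 of 28 negative (camera adjusted p = 4.50e-04, adjusted p = 0.613 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Tyms, Ccna2, Mcm5 and Top2a had values of -0.51, -0.87, -0.51 and -0.47. Mki67, which encodes the proliferation antigen Ki-67, had a value of -0.27 (SE 0.15, adjusted p = 0.744) and Ezh2, a histone methyltransferase, -0.18 (SE 0.22, adjusted p = 0.861). Nuclear genes of oxidative phosphorylation were lower by a small amount, with 35 of 37 negative and a median of -0.16 (camera adjusted p = 1.28e-05, adjusted p = 0.628 with an estimated correlation), and 0 passed either adjustment. Cyc1, Ndufs7, Ndufa9 and Ndufv2 had values of -0.42, -0.37, -0.23 and -0.22. The mean deviation was -0.34 in KO 3, where the ribosomal RNA share was highest at 18.5%, and 0.14 in KO 2. That call ended without KO 3 (adjusted p = 0.258).

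Exocytosis and calcium channel genes were higher, with 16 of 22 positive (camera adjusted p = 0.00344, adjusted p = 0.628 with an estimated correlation). None passed over all genes, and 1 rose when adjusted over the list alone, the L-type calcium channel gene Cacna1c (log2 fold change 0.77, SE 0.14). Pclo, Cacna1a and Rims2 had values of 0.69, 0.36 and 0.30. Cholesterol synthesis genes were higher, with 19 of 23 positive (camera adjusted p = 0.00318, adjusted p = 0.613 with an estimated correlation) and 0 past either adjustment. Hmgcs1, Insig1 and Srebf2 had values of 0.32, 0.26 and 0.22. Both calls ended with the ribosomal RNA covariate (adjusted p = 0.491 and 0.625).

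The remaining called lists were lower in KO. For p53 targets, with 15 of 22 negative, the camera adjusted p was 0.0145 (adjusted p = 0.497 with an estimated correlation). None passed over all genes, and adjusted over the list alone 2 fell, Plk3 (-0.77) and the cell-cycle inhibitor Cdkn1a (-0.74), and 1 rose, Trp53inp1 (0.45). Sesn2 had a value of -0.27. In the dedifferentiation list 10 of 14 were negative (camera adjusted p = 0.0153, adjusted p = 0.497 with an estimated correlation), and Aldh1a3 was the 1 gene that fell by either adjustment. Neurog3, Cd81 and Aass had values of -0.53, -0.19 and -0.53. Oxidative stress genes had 21 of 23 negative (camera adjusted p = 0.0194, adjusted p = 0.613 with an estimated correlation), with 0 past either adjustment, and included Hmox1 at -0.61, Gclc at -0.26, Srxn1 at -0.22 and Txnip at 0.58. Genes normally silenced in beta cells had 18 of 23 negative (camera adjusted p = 0.0047, adjusted p = 0.628 with an estimated correlation), with 0 past either adjustment, and included Ldha at -0.59, Lmo4 at -0.52, Acot7 at -0.53 and Oat at -0.31. Their mean deviation was -0.53 in KO 2, where that of the fibroblast list was -1.51, and 0.10 and 0.06 in KO 1 and 3. All 6 PDGF ligand and receptor genes had negative values (camera adjusted p = 0.0491, adjusted p = 0.628 with an estimated correlation), among them Pdgfb at -0.39 and Pdgfa at -0.23, with 0 past either adjustment. Without KO 2 the calls of the silenced genes (adjusted p = 0.826), of PDGF genes (adjusted p = 0.663) and of dedifferentiation (adjusted p = 0.0773) ended. Without control 1 those of the silenced genes (adjusted p = 0.0720) and of p53 targets (adjusted p = 0.0530) ended, without control 2 that of PDGF genes (adjusted p = 0.340), and without KO 3 that of oxidative stress (adjusted p = 0.258). With RLE normalization the PDGF call ended (adjusted p = 0.0507). All 5 calls ended with the ribosomal RNA covariate (adjusted p from 0.112 to 0.874).

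**Figure D3:**
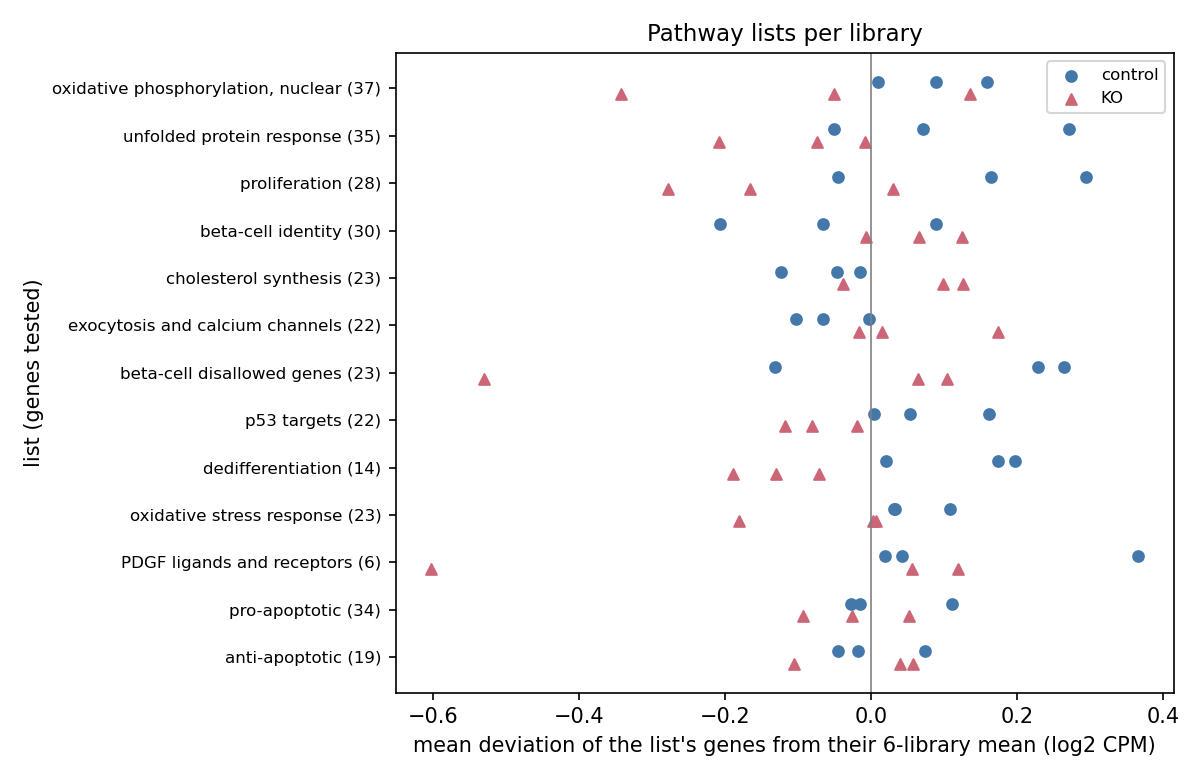
Mean deviation of each pathway list's genes from their 6-library mean, in log2 CPM, for the 11 called lists and the 2 apoptosis lists, with control libraries as circles and libraries labelled KO as triangles. The groups separate for p53 targets, dedifferentiation and oxidative stress, and 1 KO library lies far to the left for the silenced genes and the PDGF list.

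The lists not called, with their camera adjusted p, were interferon response and MHC class I (0.373), PRC2, Rb and cell-cycle entry (0.373), MAPK feedback and immediate early genes (0.569), glycolysis (0.636), hypoxia (0.879), NF-kB and inflammation (0.879), and the prolactin and growth hormone receptor response (0.879). In the last, Cish and Tph2 had values of 1.11 (edgeR adjusted p = 0.673) and 0.75 (adjusted p = 0.674), and Matn2 and Wipi1 of -0.35 and -0.16. The value of Cish leaned on KO 3, with 5.57, 9.98 and 25.1 CPM in KO 1, 2 and 3. It ran from 0.28 to 1.49 with a library left out.

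The preparations held RNA of other pancreatic cells. Genes of the acinar list, mostly digestive enzymes, took 35.7 ± 10.1% of counts in controls and 28.9 ± 8.3% in KO (SD, n = 3 each, exact two-sided permutation p = 0.5), and Ins1 and Ins2 together took 10.2 ± 3.2% and 10.6 ± 1.1% (exact two-sided permutation p = 0.9). A ribosomal RNA locus, CT010467.1, took 4.07 ± 0.66% in controls and 12.2 ± 6.6% in KO (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible), from 5.36% in KO 1 to 18.5% in KO 3. The 95% Wilson interval of any such share in a library was at most 0.0252 percentage points to either side, which covers counting error only.

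**Figure D4:**
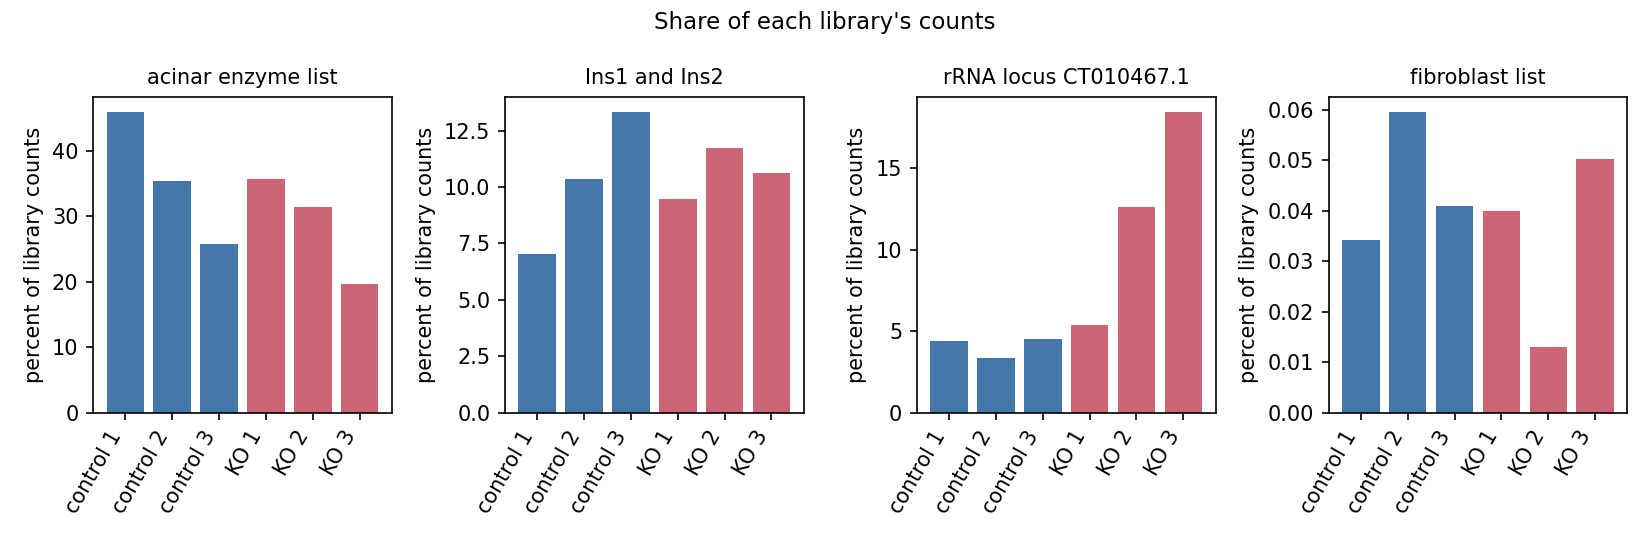
Percent of each library's counts in the acinar list, in Ins1 and Ins2, at the ribosomal RNA locus CT010467.1 and in the fibroblast list, with controls in blue and libraries labelled KO in red. The ribosomal RNA share is above all controls in each KO library, and the fibroblast share is lowest in KO 2.

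Of 13 tested cell type lists, 2 were called. Fibroblast and stellate cell genes had 20 of 23 negative values (camera adjusted p = 0.00338, adjusted p = 0.918 with an estimated correlation), with 0 past either adjustment, among them Loxl1 at -0.73, Lum at -0.63, Gsn at -0.26 and Pi16 at 0.85. The call ended without control 2 (adjusted p = 0.255), and without KO 2 it ended with the opposite direction (adjusted p = 0.513). Acinar genes had 30 of 31 negative values (camera adjusted p = 0.01003, adjusted p = 0.918 with an estimated correlation), with 0 past either adjustment, among them Reg1 at -0.76, Try4 at -0.68, Try5 at -0.63 and Pnliprp2 at -0.50. Trypsin genes are near-identical copies, so their counts are uncertain. The acinar call ended with the opposite direction without control 1 (adjusted p = 0.159) or KO 3 (adjusted p = 0.889). The other lists, with their camera adjusted p, were mitochondrially encoded genes (0.0741), endothelial (0.173), duct (0.263), macrophage (0.665), PP (0.665), erythroid (0.665), alpha (0.754), Schwann (0.754), delta (0.790), pericyte and smooth muscle (0.809) and lymphocyte (0.887).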

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

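The ribosomal RNA covariate and KO 1 alone against the controls were chosen after seeing the data. In the latter only the controls give the spread, and KO 1 is assumed to vary like them, so its calls bear little weight. The 10 called genes kept their direction in all 16 alternatives. The number of calls was 10 with RLE normalization and with acinar genes removed, and changed to 300 (174 higher and 126 lower) without the filter on low counts, 44 (14 and 30) with the acinar covariate, 50 (21 and 29) with DESeq2, 6 with limma-voom and 31 (10 and 21) with sample quality weights. Of the 300, 281 had also been tested with the filter. It ranged from 2 to 6 with 1 library left out, where fewer samples enter, and Foxi3 and Atf5 were called each time. With the ribosomal RNA covariate it was 0 (214 genes at an unadjusted p under 0.05), Atf5 moving from -1.70 (SE 0.13) to -1.49 (SE 0.20). With KO 1 alone, where fewer samples enter, it was 0 (448 genes at an unadjusted p under 0.05) and Atf5 stood at -1.50 (SE 0.14). With the replicate block it was 36 (11 higher and 25 lower). Deviations of same-numbered libraries correlated at 0.16, -0.16 and 0.14, and those of other pairs from -0.24 to 0.16. With 3 libraries per group, a pairing by number is neither shown nor excluded. Pathway list calls were 11, from 7 (without KO 2) to 12 with a library left out (interferon genes called as higher without control 3, adjusted p = 0.00826, and without KO 3, adjusted p = 0.0243), 6 with the ribosomal RNA covariate (4 of the 11, and interferon and MAPK genes as higher), 5 with KO 1 alone (3 of the 11, and the same 2; without KO 1 the MAPK genes were called as lower, adjusted p = 0.00691), and 0 with an estimated correlation or with fry. Cell type list calls were 2, from 1 (without control 2) to 3 with a library left out (endothelial, erythroid, pericyte and mitochondrially encoded genes as lower and Schwann genes as higher, each in 1 or 2 of these), 5 without the filter, 3 with the replicate block, 1 with acinar genes removed, 1 with the ribosomal RNA covariate (macrophage genes as higher, neither of the 2), 3 with KO 1 alone (neither of the 2), and 0 with an estimated correlation or with fry. Apart from the shifts whose construction shows fewer samples or genes, the cause was not tested. Among the named genes, directions turned only in those that passed no test in the main comparison. With a library left out, the log2 fold change ran from -0.589 to 0.0435 for Pdgfra, from -0.0836 to 0.0452 for Pdx1, from -0.0319 to 0.255 for Ins2, from -0.177 to 0.0483 for Sst and from -0.121 to 0.0768 for Gcg. Without a change of direction it ran from 0.00861 to 0.390 for Birc6, from 0.00262 to 0.270 for Ins1, from -0.335 to -0.0686 for Ezh2 and from -0.439 to -0.104 for Pdgfa. With the ribosomal RNA covariate the values were -0.555 for Cish, -0.109 for Birc6, 0.0976 for Pdgfa, 0.147 for Ezh2, -0.0141 for Ins1, -0.00624 for Ins2 and 0.0971 for Gcg. With KO 1 alone they were -0.181 for Cish, -0.0520 for Birc6, 0.0962 for Pdgfa, 0.0694 for Ezh2, -0.0755 for Ins1, -0.0943 for Ins2 and 0.00566 for Gcg. Gcg was at 9.55e-04 with the replicate block and 0.0181 with limma-voom. Over 85 named genes and all settings, 1222 of 1356 values kept their direction and their side of the threshold. Most of these genes were not called in the main comparison, so that count says little about the calls. In 65 of the values the threshold was lost, all of them in the 10 called genes, the only ones that could lose it. In simulated counts 62.2% of genes with a log2 fold change of 1 were recovered, so smaller changes can be missed at this depth and number of libraries. The simulated genes varied independently, and the libraries did not differ in acinar, stromal or ribosomal RNA. Recovery in the real libraries may therefore be lower.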

Other observations

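The lists and tests in this part were chosen after the results were seen, apart from the counts over other splits of the libraries. Targets of ATF4 and of the amino-acid response were lower in the libraries labelled KO: 37 of 37 tested genes had negative values, with a median of -0.51, 2 fell over all genes and 19 fell adjusted over the list alone (camera adjusted p = 5.45e-41, adjusted p = 0.0368 with an estimated correlation). It shares 9 genes with the unfolded protein response list, all negative with a median of -0.46, while the other 26 genes of that list had a median of -0.06. Atf3, in the unfolded protein response list but not among the ATF4 targets listed here, had a value of 0.11 (SE 0.39). Since some members were seen before the ATF4 list was written, neither its p nor its 37 of 37 is independent evidence. Mthfd2, a mitochondrial folate enzyme, had a log2 fold change of -1.14 (SE 0.17, edgeR adjusted p = 0.0845), Slc7a5, an amino-acid transporter, -0.80 (SE 0.11, adjusted p = 0.0665), and Psat1, an enzyme of serine synthesis, -0.98 (SE 0.23, adjusted p = 0.387). Each of them passed with the acinar covariate and with DESeq2, while no gene passed with the ribosomal RNA covariate. Cytosolic tRNA synthetases had 20 of 20 negative values with a median of -0.40 (camera adjusted p = 6.47e-27, adjusted p = 0.0518 with an estimated correlation), 11 of which fell adjusted over the list alone, among them Sars at -0.72 and Mars at -0.88. The 16 mitochondrial synthetases had a median of -0.02, with 9 negative (camera adjusted p = 0.983). Lars2, a mitochondrial synthetase left out of that list, took 0.297 ± 0.072% of counts in controls and 0.955 ± 0.525% in KO (SD, n = 3 each, exact two-sided permutation p = 0.1), and like that of the ribosomal RNA locus its share of counts was above all controls in each KO library. In KO 1, 2 and 3 Lars2 took 0.44, 0.93 and 1.49% and the locus 5.36, 12.6 and 18.5%. In controls 1, 2 and 3 Lars2 took 0.38, 0.26 and 0.25% and the locus 4.38, 3.32 and 4.51%. Whether the reads counted for Lars2 are its own transcripts was not tested. The 25 chaperone and folding genes of the endoplasmic reticulum had a median of -0.08 (camera adjusted p = 0.138).

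A cluster of 12 tested zinc finger genes on chromosome 2 (176708328 to 178034022) had 12 negative values, with a median of -0.88, and its summed level was 52.0 ± 0.68 CPM in controls and 26.9 ± 2.5 in KO (SD, n = 3 each, camera adjusted p = 1.13e-23, adjusted p = 0.00625 with an estimated correlation). The cluster was drawn up after genes in it were seen to be lower, so its p is not independent evidence. Of its genes, 1 was among the 10 calls of the main comparison. The other 343 tested Zfp genes had a median of 0.09. How reads that map to several places were treated is not given, so the 12 values of the cluster may not be separate falls. Genes regulated by cell activity, also listed after the results were seen, were higher, with 16 of 25 positive and 4 that rose adjusted over the list alone (camera adjusted p = 1.16e-05, adjusted p = 0.0368 with an estimated correlation), among them Npas4 at 2.78 (SE 0.44, edgeR adjusted p = 0.0923) and Rgs2 at 1.45 (SE 0.28, adjusted p = 0.178). The list fixed earlier for MAPK feedback and immediate early genes, which shares 9 of these genes, was not called and had 13 of 22 negative (camera adjusted p = 0.569). The 7 plasma cell genes gave a camera adjusted p = 0.223. Adjusted over that list alone 2 rose, Igha at 3.14 (SE 0.60) and Jchain at 1.64 (SE 0.59), and 1 fell, Ighm at -1.27 (SE 0.45).

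The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. For genes, 1 split, the real one, gave as many as 10 calls, and the highest other gave 0. For pathway lists it was 1 split, with 11 calls against 9 at most in the others. For cell type lists all 10 splits gave as many as the real 2, and the highest gave 9, so a structure of the samples that does not follow genotype is possible. These counts are at the preset correlation of 0.01. The estimated one was 0.92 for the acinar, 0.90 for the fibroblast and 0.79 for the oxidative phosphorylation list. It was 0.57 for beta-cell identity, 0.48 for PDGF genes, 0.44 for the silenced genes, 0.26 for exocytosis and 0.25 for proliferation. For the unfolded protein response and for cholesterol synthesis it was 0.20. Among lists chosen after the results were seen, it was 0.40 for ATF4 targets and 0.62 for cytosolic synthetases. The preset p of all these lists is too small. For p53 targets and dedifferentiation the estimated correlation was 0.009 and -0.03, below the preset. Their unadjusted camera p still rose, from 0.0058 and 0.0069 with the preset to 0.0497 and 0.0454 with the estimate. A higher p with an estimated correlation is thus not due to correlation between genes alone. With an estimated correlation each split gave 0 lists, the real one included, and the same limit holds for that count.

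The lower ATF4 targets were weighed against acinar RNA, ribosomal RNA content and the confounding of genotype with Cre or processing. The mean log2 CPM of the list differed by -0.60 (SE 0.21) between the groups. With the acinar score as a covariate it differed by -0.50 (SE 0.06), which argues against acinar RNA as the whole cause. Within each group the list score followed the acinar score. In controls both were highest in control 1 (4.99 and 11.5) and lowest in control 3 (4.39 and 10.1), and in KO both were lowest in KO 3 (3.83 and 9.95). Which cells the RNA of these targets came from was therefore not settled. With log2 CPM of the ribosomal RNA locus as a covariate the list's mean differed by -0.61 (SE 0.38), an error too wide to decide. Ribosomal RNA content thus cannot be told apart from genotype, although KO 1, at 15.7 for the locus against 14.9 to 15.7 in controls, had a list score of 4.12 against 4.39 to 4.99. With 0 control libraries that carry Cre or the KO column suffix, Cre or processing rather than Pdgfra loss stays open, as does Pdgfra loss itself.

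For Pdgfra, which was not measurably lower in KO, a candidate explanation is RNA from stromal cells that the Cre line does not target. Over the 6 libraries Pdgfra followed the rest of the fibroblast list, Pearson r = 0.984 (exact permutation p = 0.0139) and Spearman rho = 0.771 (exact permutation p = 0.103), with 1 relation tested. Without KO 2 and control 2, the farthest from the median, r was 0.781. With the fibroblast score as a covariate the difference in Pdgfra was -0.0043 (SE 0.12), so the data are consistent with stromal cells as its main source. Reads from exons that remain after deletion stay open too, because the 100 exon intervals of Pdgfra are summed into 1 count.

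For Foxi3, reads of an overlapping annotated gene are argued against, since 0 other genes in the table overlap its span. A change at the locus, such as an insertion of the Cre transgene, a copy number change or a linked variant, may be the source. Of 6 tested genes within 0.5 Mb, 2 were higher at an unadjusted p under 0.05. They were Eif2ak3 at 0.66 (SE 0.20, edgeR adjusted p = 0.537) and Igkc at 1.32 (SE 0.57, adjusted p = 0.674). Eif2ak3 passed with the acinar covariate (0.83, edgeR adjusted p = 0.00886) but not with DESeq2. Igkc is an antibody gene that plasma cells express, so its rise need not come from the locus. Igha, on chromosome 12, was higher as well (3.14, SE 0.60), while Ighm, on the same chromosome as Igha, was lower (-1.27, SE 0.45). The labels do not give the insertion site of the transgene. A response to Pdgfra loss cannot be told apart from a change at the locus.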
